A study of Mus musculus with 8 samples.

How the data were processed

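RNA sequencing was made from hippocampal tissue of adult mice in 8 libraries, 4 labelled WT and 4 labelled Kat6a+/-. Per the labels' protocols, total RNA was isolated with Trizol, treated with DNase and made into libraries with the NEBNext Ultra II RNA kit. Sequencing used an Illumina NovaSeq instrument, per the labels. The labels give no age beyond adult, no sex, no litter and no batch. Per the submitters' processing notes, STAR 2.5, HTSeq and DESeq2 were used and the genome build was GRCm38 (mm10); the role of each tool, the annotation release and whether counting used the strand are not given in the sources used here. Without stated strand, reads of overlapping genes cannot be assigned with certainty.

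The deposited table of all genes holds FPKM values per gene and library, made by the authors, with a gene length and coordinates for each of 54532 genes, per the file headers. The second table holds the authors' own comparison for 605 genes. Per the file headers it gives whole read counts per library as deposited, the authors' FPKM, their log2 fold change, and their unadjusted and adjusted p-values. It also gives a normalised signal, which the deposited values show to be the read count divided by 1 size factor per library. Every gene of the authors' deposited table has an unadjusted p under 0.05.

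The FPKM values are not scaled to each library's own total. Multiplied by the gene length and by 1 constant per library, 100% of the values of the deposited FPKM table came out as whole reads within a tolerance of 0.01, and these reads equal the deposited counts for the genes of the second table. The constants follow DESeq2-type size factors, which run from 0.833 to 1.45. FPKM therefore compares libraries after median-of-ratios scaling, and a second scaling of that kind moves nothing. FPKM also divides by gene length, so genes under 200 bases held 5.59% to 16.6% of the FPKM sum of a library with 0.0912% to 0.296% of its reads. Library totals, summed from the recovered reads, ran from 16462428 to 27875310. DESeq2 on the recovered reads of the 28210 genes with over 1 read gave log2 fold changes within 6.61e-06 and adjusted p-values within 1.05e-04 of the authors' deposited table.

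Before the data were examined, the groups, the tests, the gene lists, the rule for named genes and most alternatives were fixed. Because the main unit is FPKM, the main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with a trend of the prior variance on mean expression, on genes with a mean of at least 0.5 FPKM over the 8 libraries. This left 14159 genes, of which 12423 are protein-coding. Fold changes on this scale understate the change of low genes. The model held genotype alone, tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. For single genes an exact permutation test of the difference of mean log2 values over all 70 assignments stood beside limma; its smallest two-sided p is 0.0286. Count tests were possible on the recovered reads: limma-voom was planned, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were added after the data were seen.

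A total of 44 gene lists covered the KAT6A complex and other chromatin enzymes, the Wnt pathway, hippocampal fields, cell types of the hippocampus and of tissue beside it, neuronal function, stress, immunity and housekeeping. Lists with at least 3 measured members were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over 43 lists; the sex-linked list served as a check of the animals and was left out. Camera with an estimated correlation and the fry rotation test were alternatives. A list's score in a library is the mean over its tested members of the log2 value minus that gene's mean over the 8 libraries. Members were also adjusted over the list alone. Genes within 5 Mb of Kat6a were compared by their median with 10000 random lists matched on mean expression.

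Named genes were Kat6a and Rspo2 always, and up to 12 per direction with the largest fold change among called genes with a mean of at least 1 FPKM, a symbol that is not a predicted gene model and no overlap between the groups. As no gene qualified in limma, the 5 with the smallest unadjusted p in each direction were named and reported as not past the threshold. Up to 4 called members per list, or 2 with the smallest p where none was called, and up to 5 genes per direction with the smallest adjusted p in the authors' deposited table were also named. Further list members are named where a count of 5 or fewer or a single library rests on them, and were chosen after their values were seen.

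The limma, edgeR, limma-voom and DESeq2 steps were tested on simulated reads drawn from these libraries' means and totals for the comparison of Kat6a+/- with WT, with 14159 genes in each simulation. Over 3 simulations limma called 63.7% of genes changed by 0.5 on the log2 scale, 84.6% of those changed by 1 and 98.0% of those changed by 2; edgeR called 73.1%, 91.5% and 99.0%. In 1 simulation DESeq2 called 74.6%, 86.6% and 97.0%. Each simulation changed 67, 67 and 66 genes by 0.5, 1 and 2 at once, chosen from genes above a minimum of reads. An adjusted threshold is easier to pass when many genes change together. The draws also held no structure between libraries beyond genotype and depth. These shares therefore do not give the power of the real comparison. Of unchanged genes limma called 31 of 41823, edgeR 38 of 41823 and DESeq2 18 of 13940. A shift of -0.1 given to the interneuron list was called by camera in 3 of 3 simulations with the preset and in 0 of 3 with an estimated correlation. Of 126 tests of the other lists 0 were called, although lists that share members with the interneuron list held some shifted genes. The simulated genes were drawn independently of each other. These counts therefore do not show how often the preset calls unshifted lists whose genes are correlated. Replicates of a genotype differed by more than counting error, with a chi-square per degree of freedom from 3.66 to 13.3 between pairs, so no library is a second copy of another of its genotype; this does not show that they came from separate animals. Pairs that included replicate 1 of either genotype gave a chi-square per degree of freedom from 10.5 to 13.3, and all other pairs 3.66 to 6.56. No library was left out of the main tests. The result of 1 gene is not reported.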

Results

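Transcript levels were measured by RNA sequencing in hippocampal tissue of adult mice, 4 libraries from wild-type animals (WT) and 4 from animals heterozygous for Kat6a (Kat6a+/-). KAT6A is a histone acetyltransferase of the MYST family. The study's title places its effect on cognition in RSPO2/Wnt signalling of the CA3 field, so Kat6a, Rspo2, the Wnt pathway and the CA3 markers were examined first. Depth was 19673973, 16462428, 22047643 and 18349374 reads in WT replicates 1 to 4 and 27875310, 20621422, 17734438 and 17730609 reads in Kat6a+/- replicates 1 to 4. Of 54532 genes listed, 30875 had a read in at least 1 library, and 14159 with a mean of at least 0.5 FPKM over the 8 libraries were tested. The labels do not state that each library came from a separate animal, so the p-values measure the spread between these libraries, part of which may be technical.

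Kat6a was lower in the heterozygotes, with no overlap between the genotypes. It measured 9.35, 8.97, 8.55 and 9.71 FPKM in the WT libraries and 6.06, 7.64, 7.32 and 7.06 FPKM in the Kat6a+/- libraries, which is 9.15 ± 0.498 FPKM against 7.02 ± 0.683 FPKM (mean ± SD, n = 4 each). The heterozygote mean was 76.7% of the WT mean, and every library matched its genotype label by this measure. The log2 fold change on the log2(FPKM + 0.5) scale was -0.36 ± 0.07 (SE), with a 95% interval from -0.52 to -0.20. An exact two-sided permutation test of the 4 against 4 values gave p = 0.0286, the smallest that the design allows. Across all tested genes limma gave an adjusted p of 0.9998 for Kat6a, while DESeq2 on the recovered reads of the same genes, an analysis chosen after the data were seen, gave an adjusted p of 0.00639. Kat6a (ENSMUSG00000031540) lies on chromosome 8 from 22859535 to 22943259 on the plus strand of GRCm38, and between 1129 and 1736 reads per library stood behind its values.

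**Figure D1:**
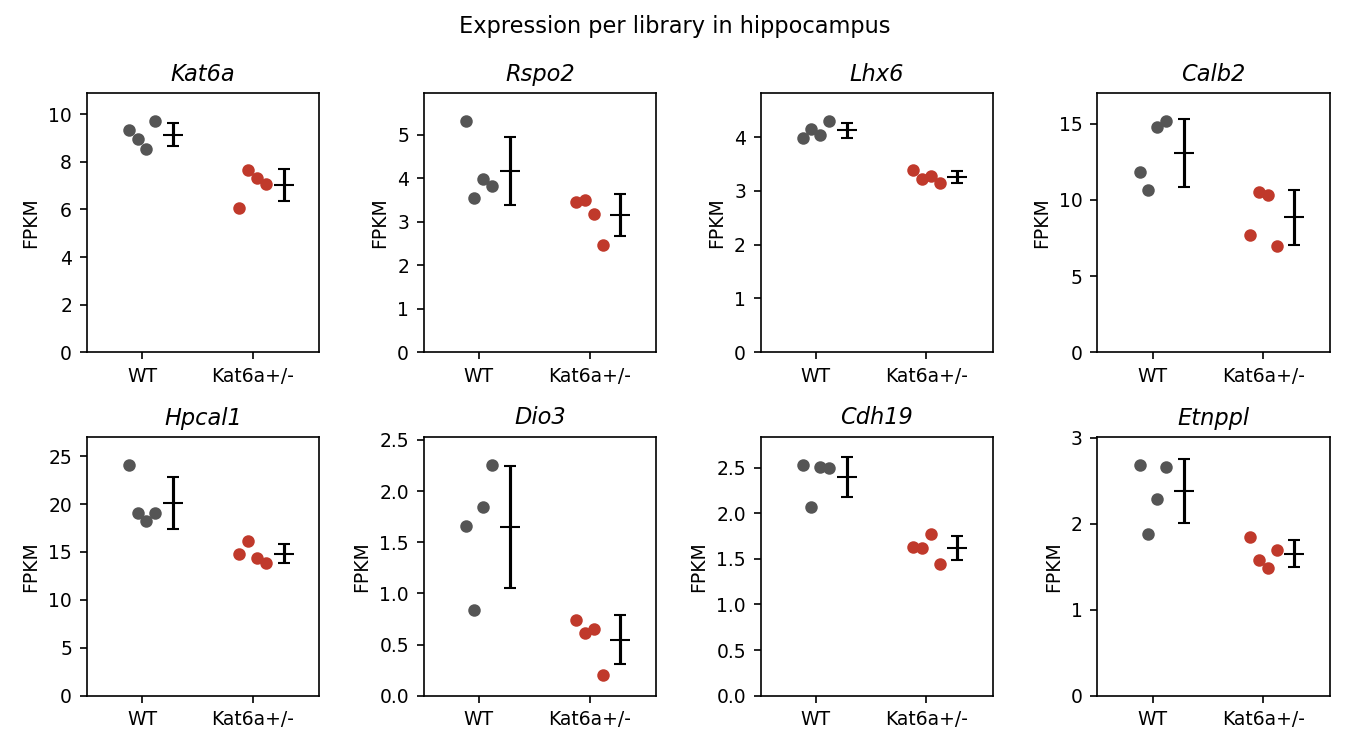
FPKM of 8 genes in each hippocampal library, 4 WT (grey points) and 4 Kat6a+/- (red points), with the mean and SD of each group as a black bar beside the points and every axis starting at 0. Kat6a lies between 8.55 and 9.71 FPKM in WT and between 6.06 and 7.64 FPKM in Kat6a+/-, and the groups do not overlap in any of the panels.

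Beyond Kat6a itself, the protein-coding genes with the smallest p in limma were lower in the heterozygotes. Cdh19, an adhesion molecule of the cadherin family, measured 2.40 ± 0.221 FPKM in WT and 1.62 ± 0.132 FPKM in Kat6a+/- (SD, n = 4 each). Lhx6, a transcription factor of interneurons born in the medial ganglionic eminence, measured 4.13 ± 0.135 FPKM against 3.26 ± 0.106 FPKM, and Irak2, a kinase of interleukin-1 and Toll-like receptor signalling, 4.05 ± 0.128 FPKM against 3.20 ± 0.201 FPKM. Among protein-coding genes Tipin, a factor of the replication fork, was the one with the smallest p in the other direction, at 4.07 ± 0.139 FPKM in WT and 5.09 ± 0.468 FPKM in Kat6a+/-. None of these values passed the threshold in limma.

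In limma 0 of the 14159 tested genes passed an adjusted p of 0.05, in either direction. At an unadjusted p under 0.05 there were 624 genes, 252 higher and 372 lower in Kat6a+/-, where chance alone gives 708. The recovered reads gave 0 called genes with edgeR (616 at an unadjusted p under 0.05) and 0 with limma-voom (600). DESeq2 called 5 of the same genes, all lower (Cdh19, Dio3, Etnppl, Hpcal1 and Kat6a), with 467 genes at an unadjusted p under 0.05. The 4 Kat6a+/- values all lay above the 4 WT values in 155 genes and all below them in 216 genes, which is 1.09% and 1.53% of the tested genes, where chance gives 2.86% for both directions together.

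The remaining genes with the smallest p in limma were not protein-coding. Gm25654, a small nuclear RNA gene of 88 bases inside Aaed1 on the same strand, had the lowest adjusted p, 0.194, and rested on 7 reads over the WT libraries and 0 over the Kat6a+/- libraries. It passed the limma threshold without WT replicate 3 (adjusted p = 0.0138). In the other direction stood Gm22965, a small nuclear RNA gene with 5 reads over WT and 23 over Kat6a+/-, the processed pseudogene Gm9800 with 57 and 91 reads, Gm17066 inside Rbm26 with 303 and 457 reads, and the microRNA gene Mir5125 inside Srrm2 with 154 and 294 reads. Gm17066 and Mir5125 share their strand with the surrounding gene, so their reads cannot be told from reads of Rbm26 and Srrm2, and the source of reads counted for Gm9800 is uncertain because a pseudogene resembles its parent gene.

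The authors' deposited table of their own comparison holds 605 genes, 267 higher and 338 lower in Kat6a+/-. Kat6a is the one gene there with an adjusted p under 0.05, at a log2 fold change of -0.38 and an adjusted p of 0.0166 in the authors' deposited table. The next genes of the authors' deposited table by adjusted p are also lower: Dio3, the deiodinase that inactivates thyroid hormone, at a log2 fold change of -1.57 and an adjusted p of 0.0709, Hpcal1, a neuronal calcium sensor, at -0.44 and 0.0709, Cdh19 at -0.57 and 0.0709, and Etnppl, an astrocytic phospholyase of phosphoethanolamine, at -0.53 and 0.113. Of the higher genes, Cdhr3 leads the authors' deposited table at a log2 fold change of 1.44 and an adjusted p of 0.113. Mir5125, Grem1, Cdh24 and Erfe follow there with an adjusted p of 0.9998.

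The FPKM values behind these genes separated the genotypes in most cases. Dio3 measured 1.65 ± 0.598 FPKM in WT and 0.549 ± 0.240 FPKM in Kat6a+/-, Hpcal1 20.1 ± 2.68 FPKM and 14.8 ± 1.0 FPKM, and Etnppl 2.38 ± 0.377 FPKM and 1.65 ± 0.157 FPKM (SD, n = 4 each). Cdhr3, at 0.174 ± 0.0829 FPKM against 0.476 ± 0.0838 FPKM, fell below the level needed for testing in limma. Erfe was listed at 0 in all 4 WT libraries and had 11, 8, 1 and 1 reads in the Kat6a+/- libraries. Grem1, a secreted BMP antagonist, measured 1.47 ± 0.239 FPKM against 2.06 ± 0.229 FPKM, with overlapping groups. Of the 605 genes, 434 were tested in limma. All 434 had the same direction, 0 passed the adjusted threshold and 342 had an unadjusted p under 0.05. The 605 genes were selected by their unadjusted p in the same reads. Their separation, direction and low p in limma follow from that selection and are no independent support. The 605 genes amount to 2.14% of the 28207 tests that the adjusted p-values of the authors' deposited table imply, where chance alone gives 5%, and the largest unadjusted p among them is 0.04997. These tests include genes below the minimum of 0.5 FPKM, some with few reads such as Erfe, for which 5% need not hold. DESeq2 on the genes above that minimum gave 3.30% at an unadjusted p under 0.05.

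Rspo2, a secreted R-spondin that amplifies Wnt signalling, was the second question. Its values were 5.31, 3.56, 3.97 and 3.82 FPKM in WT and 3.45, 3.51, 3.19 and 2.47 FPKM in Kat6a+/-, which is 4.17 ± 0.783 FPKM against 3.15 ± 0.476 FPKM (SD, n = 4 each), or 75.7% of the WT mean. The groups did not overlap, although 3.56 FPKM in WT replicate 2 and 3.51 FPKM in Kat6a+/- replicate 2 lay next to each other. The log2 fold change was -0.35 ± 0.13 (SE), with a 95% interval from -0.63 to -0.06, and the exact two-sided permutation p was 0.0286, the smallest possible here. The gene did not pass in limma (adjusted p = 0.9998), and the authors' deposited table gives it a log2 fold change of -0.40 with an adjusted p of 0.9998. Without WT replicate 1, which held the highest value, the log2 fold change of Rspo2 in limma was -0.24. Rspo2 (ENSMUSG00000051920) lies on chromosome 15 from 43020794 to 43170826 on the minus strand.

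The pathway around Rspo2 held values in both directions. Of 19 measured R-spondins, Wnt receptors and regulators, 9 were higher and 10 lower, with a median log2 fold change of -0.01 (-0.04 to 0.05 when leaving out each replicate), and the list did not differ from other genes (camera, adjusted p = 0.598). Its members with the smallest p were Fzd1, a Frizzled receptor, at 3.41 ± 0.211 FPKM in WT and 2.79 ± 0.190 FPKM in Kat6a+/-, and Kremen1, a receptor of Dickkopf proteins, at 2.69 ± 0.165 FPKM and 3.14 ± 0.207 FPKM (SD, n = 4 each). Together with Rspo2, Fzd2 and Fzd4, they made 5 members with an unadjusted p under 0.05, and 0 passed when adjusted over the list alone (lowest adjusted p = 0.0679) or over all genes. Among 10 Wnt ligands, 6 were lower (camera, adjusted p = 0.294). Their mean score was lower in each heterozygote library than in each WT library (exact permutation p = 0.0286; 0.410 after adjustment over 43 lists), with a difference of -0.04, and the fry rotation test gave an adjusted p of 0.798. Wnt5a measured 1.61 ± 0.133 FPKM in WT against 1.31 ± 0.0803 FPKM and Wnt10a 1.33 ± 0.229 FPKM against 1.05 ± 0.0749 FPKM, both without overlap. Among 13 Wnt/beta-catenin targets, 8 were lower, Axin2 measured a log2 fold change of 0.02, and the list was not called (camera, adjusted p = 0.543). Nkd2 and Myc led that list at log2 fold changes of -0.22 and -0.12, and 0 of its members passed adjusted over the list alone.

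Among markers of the hippocampal fields, those of dentate granule cells were the one called group. Of 13 dentate granule markers 12 were higher in Kat6a+/-, at a median log2 fold change of 0.12 (camera, adjusted p = 0.00130; adjusted p = 0.734 with an estimated correlation). Tdo2 measured 1.53 ± 0.184 FPKM in WT and 1.80 ± 0.112 FPKM in Kat6a+/-, Stxbp6 17.1 ± 1.08 FPKM and 18.7 ± 1.36 FPKM (SD, n = 4 each), and 0 members passed adjusted over the list alone or over all genes. The dentate call was lost without WT replicate 3 (median 0.075). CA3 pyramidal markers were higher in 10 of 13 members, at a median log2 fold change of 0.07, and were not called (camera, adjusted p = 0.0951). They were called higher in 4 of 17 alternatives. These were without WT replicate 4 (camera, adjusted p = 0.0104), without Kat6a+/- replicate 1 (0.0134), with a replicate block, and with scaling to a common sum without mitochondrial genes (0.0253). Without WT replicate 1 the adjusted p was 0.956 and the median -0.00053 (range of the adjusted p over the alternatives 0.0104 to 0.956). The highest median when leaving out each replicate was 0.13. WT replicate 1 had the lowest CA3 score of the 8 libraries, -0.20. Cdh24, the CA3 marker with the smallest p, measured 3.75 ± 0.305 FPKM in WT and 4.77 ± 0.561 FPKM in Kat6a+/-, and St18 5.48 ± 0.657 FPKM and 6.22 ± 0.573 FPKM.

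CA1 pyramidal markers were split, 6 higher and 5 lower (camera, adjusted p = 0.608), with Wfs1 at 42.5 ± 3.93 FPKM in WT and 38.2 ± 1.26 FPKM in Kat6a+/-, and Mpped1 at 56.2 ± 2.08 FPKM and 52.0 ± 3.08 FPKM. CA2 markers, led by Stard5 and Sostdc1 at log2 fold changes of 0.16 and 0.19, had an adjusted p of 0.284 in camera. Cajal-Retzius and subicular markers, 3 higher and 3 lower, had an adjusted p of 0.786 and included Ndnf at a log2 fold change of -0.19. Adult neurogenesis markers were lower in 10 of 13 members (camera, adjusted p = 0.221), with Calb2 and Mcm2 at log2 fold changes of -0.54 and 0.19. In all of these lists 0 members passed adjusted over the list alone.

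Interneuron markers were lower as a group. Of 18 measured members 15 were lower in Kat6a+/-, at a median log2 fold change of -0.10, and the mean score of the list separated the genotypes without overlap (exact permutation p = 0.0286; 0.410 after adjustment over 43 lists), as did the scores of the Wnt ligands and, in the other direction, of the mural cell markers. Camera called the list lower at an adjusted p of 9.69e-06, with an adjusted p = 0.242 with an estimated correlation. Calb2, which encodes the calcium buffer calretinin, measured 13.1 ± 2.23 FPKM in WT and 8.87 ± 1.80 FPKM in Kat6a+/-. Lhx6 and Calb2 passed when adjusted over the list alone (2 of 18 members, lowest adjusted p = 0.00290 in limma), and 0 passed over all genes. Lamp5, Reln and Sst, markers of further interneuron classes, had log2 fold changes of -0.22, -0.28 and -0.17 at unadjusted p under 0.05. Gad1, Gad2 and Slc32a1, which all classes of GABAergic neurons use, measured 94.2%, 93.1% and 95.9% of their WT means, and Adarb2 lay at 114%. Of the list's members, 7 also stand in another of the fixed lists; Calb2 also marks thalamic neurons and young granule cells.

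**Figure D2:**
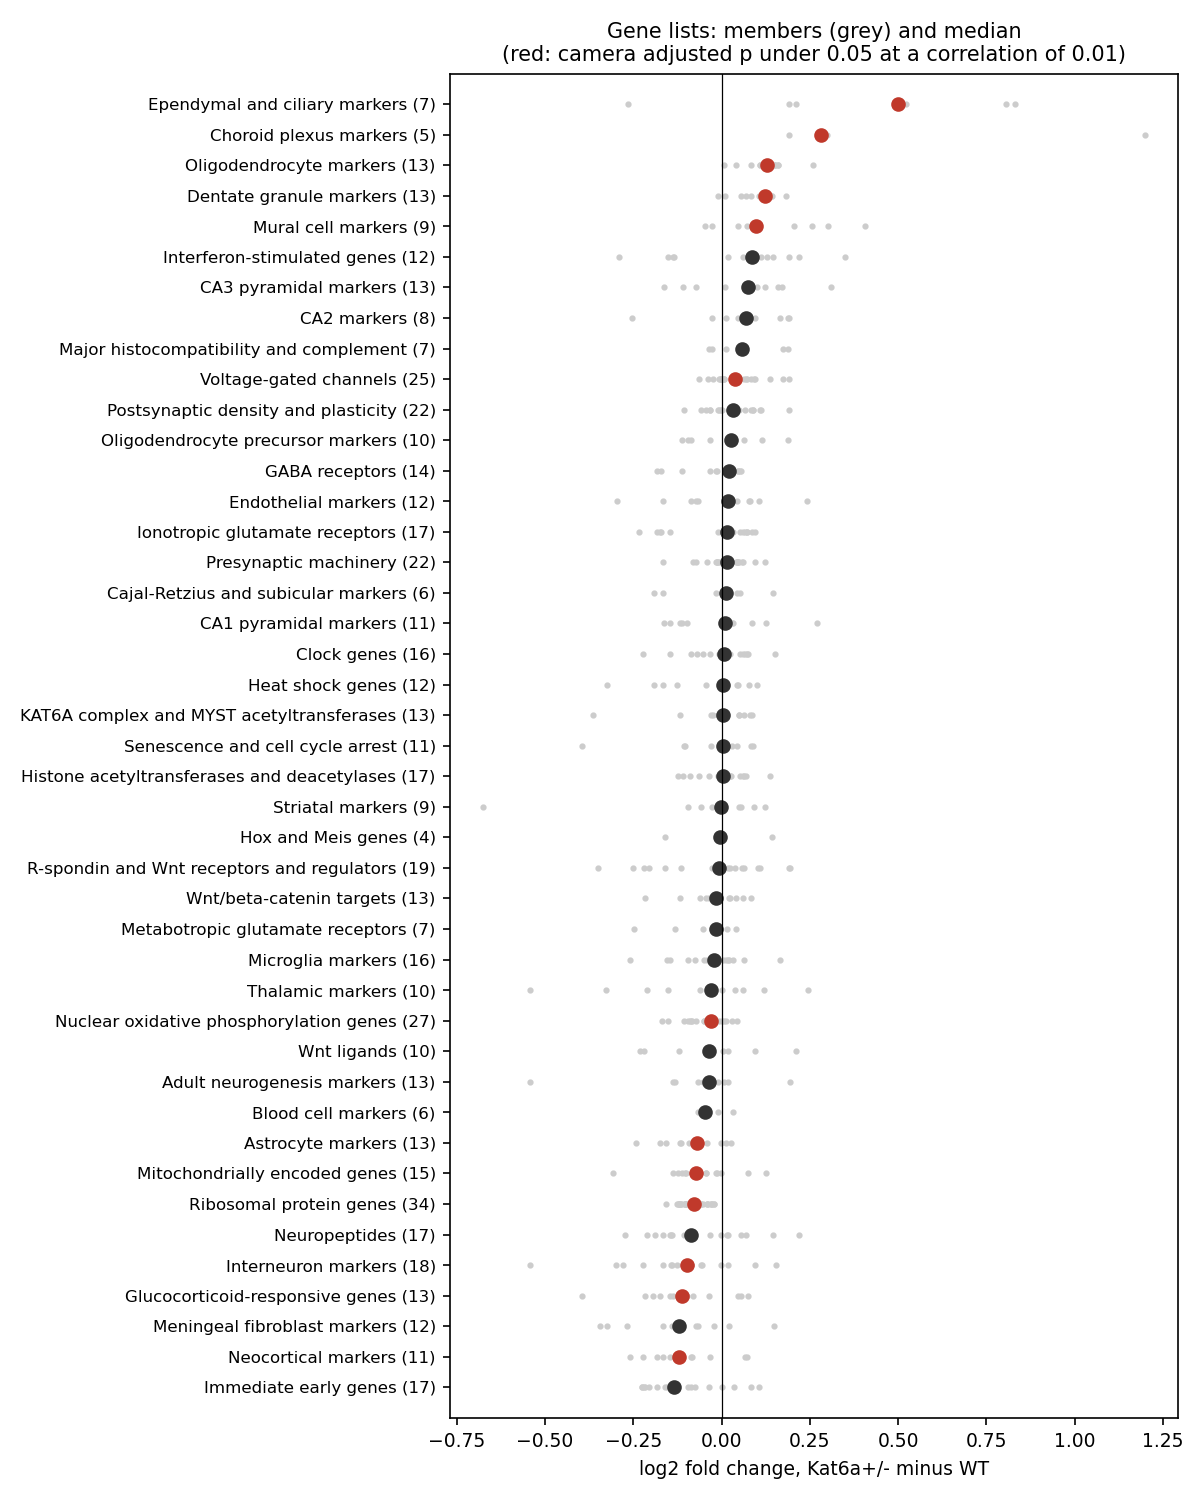
Log2 fold change, Kat6a+/- minus WT, of the measured members (grey points) and the median (large point) of each of the 43 gene lists, with the number of measured members in brackets. Red medians mark the 13 lists that camera called with a preset correlation of 0.01, 6 higher and 7 lower in Kat6a+/-; with an estimated correlation 0 lists were called.

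Glial and border tissue groups moved in different directions. Oligodendrocyte markers were higher in 13 of 13 members, at a median log2 fold change of 0.13 (camera, adjusted p = 0.00213; adjusted p = 0.803 with an estimated correlation), with Opalin at 7.66 ± 0.872 FPKM in WT and 9.33 ± 1.71 FPKM in Kat6a+/- and Mog at 27.4 ± 3.30 FPKM and 30.6 ± 3.03 FPKM (SD, n = 4 each). Astrocyte markers were lower in 11 of 13 members, at a median of -0.07 (camera, adjusted p = 0.00130; adjusted p = 0.734 with an estimated correlation), with the connexin gene Gjb6 at 22.5 ± 3.21 FPKM and 18.8 ± 0.438 FPKM and Aldoc at 254 ± 19.2 FPKM and 228 ± 11.9 FPKM. Mural cell markers were higher in 7 of 9 members, at a median of 0.10 (camera, adjusted p = 0.0208; adjusted p = 0.734 with an estimated correlation), led by Rgs5 at 11.1 ± 0.557 FPKM and 12.9 ± 1.18 FPKM and Higd1b at 0.927 ± 0.167 FPKM and 1.44 ± 0.579 FPKM. Higd1b had 12 to 34 reads per library, and Kat6a+/- replicate 4 measured 2.30 FPKM against 0.801 to 1.23 FPKM in the other libraries. WT replicate 1 had the lowest oligodendrocyte score, -0.35, and the highest astrocyte score, 0.19, of the 8 libraries. Without it the oligodendrocyte list (median 0.03, adjusted p = 0.472) and the astrocyte list (median -0.03, adjusted p = 0.0618) were no longer called. The oligodendrocyte median was 0.20 without WT replicate 3, and the astrocyte median -0.04 without Kat6a+/- replicate 1 and -0.11 without Kat6a+/- replicate 2. The oligodendrocyte call was also lost without Kat6a+/- replicate 1, and the mural call was lost without WT replicate 3, WT replicate 4 or Kat6a+/- replicate 4. The mural median was 0.03 without WT replicate 3, and 0.18, 0.16 and 0.18 without WT replicate 2, Kat6a+/- replicate 1 and Kat6a+/- replicate 2.

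Ependymal and ciliary markers were higher in 6 of 7 members, at a median log2 fold change of 0.50 (camera, adjusted p = 0.00216; adjusted p = 0.734 with an estimated correlation). Dynlrb2, a dynein light chain of motile cilia, measured 0.496 ± 0.283 FPKM in WT and 1.23 ± 0.415 FPKM in Kat6a+/-. It passed adjusted over the list alone (adjusted p = 0.0351 in limma), and 0 members passed over all genes. Dynlrb2 rested on 22 reads over WT and 55 over Kat6a+/-, with an unadjusted p of 0.0153 in edgeR and 0.0246 in DESeq2 on genes with over 1 read. Tmem212 measured 0.665 ± 0.659 FPKM and 1.42 ± 0.480 FPKM, from 39 and 89 reads. Choroid plexus markers were higher in 5 of 5 tested members, at a median of 0.28 (camera, adjusted p = 0.00181; adjusted p = 0.734 with an estimated correlation), among them Kl at 2.72 ± 0.478 FPKM and 3.45 ± 0.451 FPKM and Enpp2 at 19.7 ± 2.17 FPKM and 24.3 ± 5.06 FPKM. Ttr, the main transcript of the choroid plexus, lay at 119 FPKM in Kat6a+/- replicate 2 and between 7.61 and 20.5 FPKM in the other 7 libraries. Neocortical markers were lower in 9 of 11 members, at a median of -0.12 (camera, adjusted p = 0.0238; adjusted p = 0.734 with an estimated correlation), with Lamp5 at 11.4 ± 1.19 FPKM and 9.68 ± 0.458 FPKM and Tle4 at 12.6 ± 0.422 FPKM and 11.8 ± 0.583 FPKM. WT replicate 1 had the highest neocortical score, 0.35, and the lowest ependymal and choroid plexus scores, -0.65 and -0.44. Without it the neocortical list (median 0.01, adjusted p = 0.743) and the ependymal list (median 0.25, adjusted p = 0.0545) were not called, and the neocortical median had turned. The neocortical call was also lost without Kat6a+/- replicate 2 or 4 (median -0.07 without replicate 4). The choroid plexus median was 0.15 without Kat6a+/- replicate 2, and the choroid plexus list was not called without WT replicate 1 and Kat6a+/- replicate 2 together (adjusted p = 0.125).

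**Figure D3:**
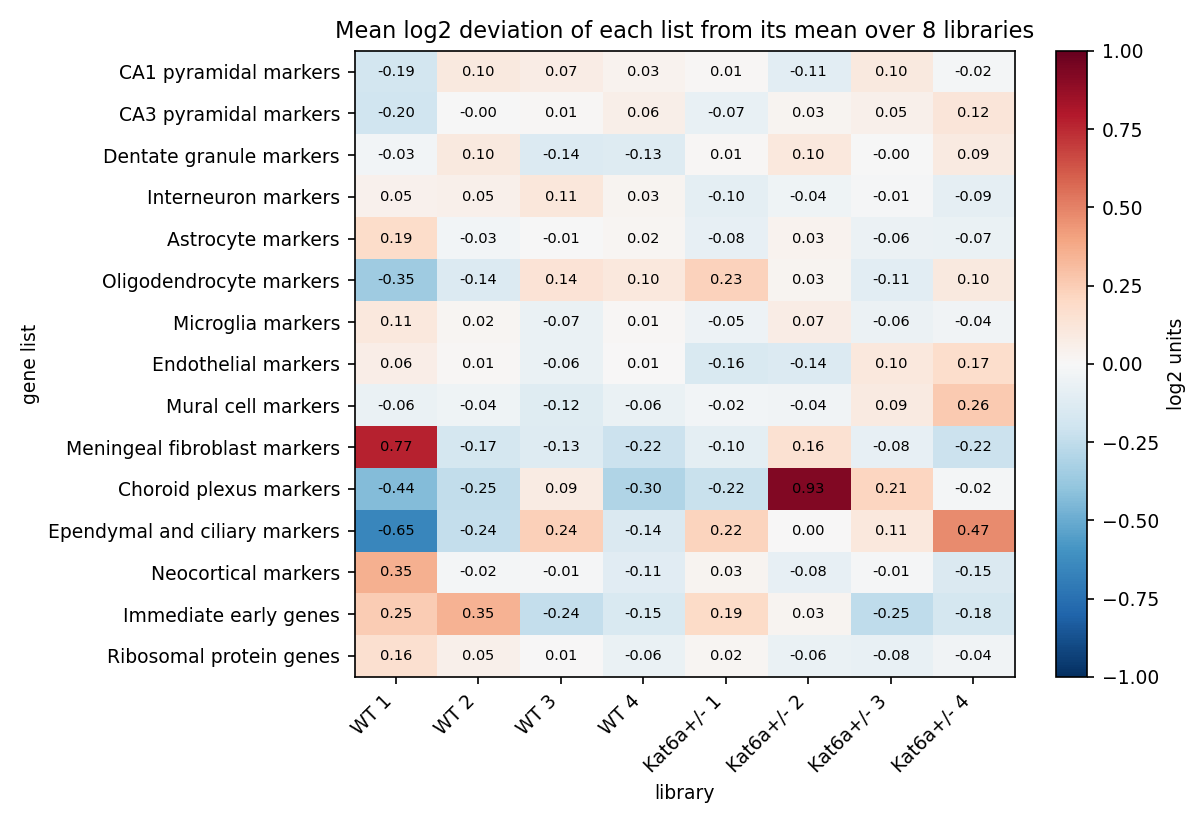
Mean log2 deviation of 15 gene lists from their own mean over the 8 libraries, with 1 column per library and the value printed in each cell. WT replicate 1 stands at 0.77 for meningeal and 0.35 for neocortical markers, and Kat6a+/- replicate 2 at 0.93 for choroid plexus markers.

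No other cell type list was called in camera. Meningeal fibroblast markers, 10 of 12 lower, had an adjusted p of 0.284, with Dcn at 4.36 ± 1.27 FPKM in WT and 3.37 ± 1.03 FPKM in Kat6a+/- and a score of 0.77 in WT replicate 1 against at most 0.16 elsewhere. Without WT replicate 1 the direction of the meningeal test turned to higher (adjusted p = 0.0545). Microglia markers (adjusted p = 0.509) held P2ry12 at 12.6 ± 0.954 FPKM and 10.5 ± 1.46 FPKM beside Trem2 at 2.04 ± 0.202 FPKM and 2.34 ± 0.122 FPKM. Endothelial markers (adjusted p = 0.873) held Pecam1 and Tek at log2 fold changes of -0.30 and 0.24, and oligodendrocyte precursor markers (adjusted p = 0.786) held Olig2 at 0.19 and Lhfpl3 at -0.11. Blood cell markers (adjusted p = 0.629), led by Hbb-bs and Hba-a1 at -0.06 each (-0.11 to -0.0084 and -0.15 to 0.10 when leaving out each replicate), striatal markers (adjusted p = 0.979) and thalamic markers (adjusted p = 0.509) did not differ. In the thalamic list Calb2 passed adjusted over the list alone, with Ramp3 at a log2 fold change of -0.33, and in the striatal list Rgs9 had a log2 fold change of 0.09 (0.03 to 0.14 when leaving out each replicate). The Y-linked genes Ddx3y and Uty were present in all 8 libraries, with Ddx3y at 11.2 ± 0.465 FPKM in WT and 11.3 ± 0.685 FPKM in Kat6a+/- (SD, n = 4 each).

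Housekeeping groups were slightly lower in the heterozygotes. Ribosomal protein genes were lower in 34 of 34 members, at a median log2 fold change of -0.08 or -5.25% (camera, adjusted p = 6.32e-09; adjusted p = 0.734 with an estimated correlation), with Rpl30 at 33.9 ± 2.03 FPKM in WT and 31.0 ± 1.68 FPKM in Kat6a+/-. Rpl13 measured 109 ± 4.04 FPKM and 102 ± 3.92 FPKM (SD, n = 4 each). Without WT replicate 1 the ribosomal median was -0.04, and without WT replicate 4 it was -0.12. Mitochondrially encoded genes were lower in 13 of 15 members, at a median of -0.07 (camera, adjusted p = 0.0118; adjusted p = 0.734 with an estimated correlation), with the ribosomal RNAs mt-Rnr1 and mt-Rnr2 at log2 fold changes of -0.14 and -0.11. Nuclear oxidative phosphorylation genes were lower in 22 of 27 members, at a median of -0.03 (camera, adjusted p = 0.0114; adjusted p = 0.814 with an estimated correlation), with Ndufa2 and Sdhb at -0.17 and -0.08. Glucocorticoid-responsive genes were lower in 10 of 13 members, at a median of -0.11 (camera, adjusted p = 0.00328; adjusted p = 0.734 with an estimated correlation), with Tsc22d3, a classical glucocorticoid target, at 23.7 ± 1.59 FPKM and 20.3 ± 1.13 FPKM and the cell cycle inhibitor Cdkn1a at 2.30 ± 0.205 FPKM and 1.65 ± 0.375 FPKM. The mitochondrially encoded median was -0.04 without WT replicate 1, -0.11 without WT replicate 2 and -0.04 without Kat6a+/- replicate 4, and the oxidative phosphorylation median -0.06 without WT replicate 4, -0.05 without Kat6a+/- replicate 1 and -0.02 without Kat6a+/- replicate 3. In these 4 lists 0 members passed adjusted over the list alone or over all genes. The mitochondrially encoded call was lost without WT replicate 1, 3 or 4 or Kat6a+/- replicate 4 and after quantile normalization, where its median was 0, the oxidative phosphorylation call without WT replicate 1, 2 or 3 or Kat6a+/- replicate 2 or 3, or without WT replicate 1 and Kat6a+/- replicate 2 together, and the glucocorticoid call without WT replicate 3. Quantile normalization gives a gene that holds the same rank in every library the same value. A median of 0 can therefore come from the method itself.

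Among neuronal function groups, voltage-gated channels were higher in 19 of 25 members, at a median log2 fold change of 0.04 (camera, adjusted p = 0.0393; adjusted p = 0.814 with an estimated correlation). Cacna1h, a T-type calcium channel, measured 14.4 ± 1.14 FPKM in WT and 16.3 ± 0.760 FPKM in Kat6a+/-, and Kcna4 5.34 ± 0.763 FPKM and 6.15 ± 0.578 FPKM (SD, n = 4 each). This call was lost without WT replicate 1 or 3 or Kat6a+/- replicate 3 or 4, or without WT replicate 1 and Kat6a+/- replicate 2 together. The channel median was -0.0010 without WT replicate 1, 0.07 without WT replicate 4, and 0.08, 0.06, 0.0089 and 0.0055 without Kat6a+/- replicates 1, 2, 3 and 4. Postsynaptic density genes, 14 of 22 higher, were not called (camera, adjusted p = 0.166), with Bdnf at 7.21 ± 0.467 FPKM and 8.31 ± 0.799 FPKM and Camk2b at 159 ± 10.8 FPKM and 172 ± 11.2 FPKM. Presynaptic genes (adjusted p = 0.786) held Stx1a and Cplx1 at log2 fold changes of -0.17 and -0.08. Ionotropic glutamate receptors (adjusted p = 0.620) held Grin2d at 2.70 ± 0.145 FPKM and 2.23 ± 0.208 FPKM and Grin3a at 4.40 ± 0.308 FPKM and 3.81 ± 0.310 FPKM, NMDA receptor subunits used by interneurons and young neurons. Metabotropic glutamate receptors (adjusted p = 0.375) held Grm3 and Grm4 at -0.13 and -0.25, and GABA receptors (adjusted p = 0.873) Gabra3 and Gabra2 at -0.18 and -0.11. Neuropeptides were lower in 11 of 17 members (adjusted p = 0.149), led by Sst and Cort at -0.17 and -0.19. Immediate early genes were lower in 14 of 17 members (adjusted p = 0.0644), led by Fosl2 at 7.20 ± 0.427 FPKM and 6.17 ± 0.380 FPKM and Fosb at a log2 fold change of -0.22. They were called lower in 5 of 17 alternatives, among them without WT replicate 3 (adjusted p = 2.67e-04), WT replicate 4 (0.0129) or Kat6a+/- replicate 1 (0.00426) and with scaling to a common sum without mitochondrial genes (0.0253). The adjusted p was 0.469 without WT replicate 1 and 0.777 without WT replicate 2 (range over the alternatives 2.67e-04 to 0.895).

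The remaining lists concerned chromatin, stress and immunity, and none was called in camera. The KAT6A complex and MYST acetyltransferases had a median log2 fold change of 0.01 over 13 members (adjusted p = 0.822); Kat6a alone passed adjusted over the list alone (adjusted p = 0.00667 in limma), and Kat5 measured 17.2 ± 0.994 FPKM in WT and 15.8 ± 0.668 FPKM in Kat6a+/-. The paralog Kat6b had a log2 fold change of 0.08. Other histone acetyltransferases and deacetylases (adjusted p = 0.822) held Hdac11, without overlap, at 31.4 ± 0.468 FPKM and 28.8 ± 0.339 FPKM, and Hdac5 at a log2 fold change of -0.11. Hox and Meis genes (adjusted p = 0.839), known targets of MYST acetyltransferases in development, were measured for 4 of 30 members, with Meis3 and Meis2 at 0.14 and -0.16 (Meis2 -0.23 to -0.06 when leaving out each replicate). Clock genes (adjusted p = 0.817) held Npas2 and Cry1 at -0.22 and -0.14 (Cry1 -0.22 to -0.06 when leaving out each replicate), heat shock genes (adjusted p = 0.303) Dnajb1 and Hspa5 at -0.19 and -0.17, and senescence genes (adjusted p = 0.509) Cdkn1a and Cdkn1b at -0.40 and -0.11. Interferon-stimulated genes were higher in 8 of 12 members (adjusted p = 0.257); Ifit3b, at 1.40 ± 0.221 FPKM and 1.91 ± 0.0850 FPKM, passed adjusted over the list alone (adjusted p = 0.0483 in limma), and Ifitm3 had a log2 fold change of 0.19. Major histocompatibility and complement genes (adjusted p = 0.509) held C4b and H2-Eb1 at 0.17 and 0.19 (0.09 to 0.25 and 0.02 to 0.33 when leaving out each replicate). Over the 43 lists, members passed adjusted over the list alone in 5 lists (Lhx6, Calb2, Dynlrb2, Ifit3b and Kat6a) and in 0 lists adjusted over all genes. In 12 of the 43 lists, none of them called, the median, the mean and the test differed in sign: heat shock, senescence, CA1, ionotropic glutamate receptor, Cajal-Retzius and subicular, clock, KAT6A complex, histone acetyltransferase, Hox and Meis, endothelial, GABA receptor and striatal genes. The direction of the test turned in at least 1 alternative in 18 of the 30 lists not called and in 0 of the 13 called lists.

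Genes beside Kat6a were compared with matched genes, since a targeted allele can carry flanking sequence of another strain. The 61 tested genes within 5 Mb of Kat6a on chromosome 8 had a median log2 fold change of 0.02 (0.0096 to 0.026 when leaving out each replicate). Among 10000 random lists of the same size matched on mean expression this median lay at percentile 95.6, inside the range that holds 95% of those lists, -0.02 to 0.02. A median cannot show flanking genes that change in opposite directions, and their spread was not tested. The comparison therefore does not exclude flanking sequence of another strain.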

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

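The counts over other splits of the libraries were planned, while the tests of choroid plexus and meningeal tissue and the counts over 18 of those splits were chosen after the result was seen. Dixon's test on 124 groups of 4 values (list scores, named genes and depth in each genotype) marked 11 values that stood apart from the other 3 of their group, where chance gives about 6.2.

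The numbers of genes at an unadjusted p and of lists that separated the genotypes were not beyond other groupings of the same libraries. At an unadjusted p under 0.05 the genotypes gave 624 genes in limma, 16 of the 35 splits of the 8 libraries into 4 and 4 gave as many, and the highest other gave 1917. For the 13 lists called by camera 8 of the 35 splits gave as many, with 16 as the highest other. Chance therefore cannot be excluded for these 2 counts. With 0 genes called in limma, 35 of 35 splits give as many whatever the data are (highest other 8), so that count tests nothing. The split that set replicates 1 and 2 of both genotypes against replicates 3 and 4 gave the 8 called genes, the 1917 genes at an unadjusted p under 0.05 and 16 lists, which points to a structure of the samples apart from genotype; the labels name no batch, and the cause was not tested. Among the 18 splits with 2 libraries numbered 1 or 2 on each side, 4 gave at least 624 genes (highest other 788) and 2 gave at least 13 lists (highest other 14), the genotypes included, so chance cannot be excluded there either.

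The meningeal fibroblast score of WT replicate 1, 0.77, stood apart from the other WT libraries at -0.22 to -0.13, and the choroid plexus score of Kat6a+/- replicate 2, 0.93, was the highest of the 8 libraries. Both libraries were picked by these scores, so the markers behind a score, such as Ptgds (252 FPKM against 82.4 to 115 FPKM elsewhere) and Ttr (119 FPKM against 7.61 to 20.5 FPKM), describe the pattern and test nothing. Of 12 further choroid plexus markers with at least 20 reads, too low to enter the score, 10 were highest in Kat6a+/- replicate 2, which is what choroid plexus tissue in 1 library would give, although markers that are regulated together would give it too. For meningeal tissue in 1 library just 2 such markers were left, 1 of them highest in WT replicate 1, which is too few to decide, so this source stays open. The labels name no step that would remove such tissue, and no biological explanation was tested for single libraries. WT replicate 1 also had the highest thalamic, striatal and Cajal-Retzius and subicular scores of the 8 libraries, 0.25, 0.25 and 0.29. Its CA1, CA2 and CA3 scores, -0.19, -0.17 and -0.20, were the lowest, while its dentate granule score, -0.03, was not. Whether this library held more tissue from beside the hippocampus was not tested.

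The remaining values that stood apart were the following. In WT replicate 1 the metabotropic glutamate receptor score was 0.19, against -0.03 to -0.01 in the other WT libraries, and Hpcal1 measured 24.1 FPKM, against 18.3 to 19.1 FPKM. In WT replicate 2 Cdh19 measured 2.07 FPKM, against 2.49 to 2.53 FPKM, and Irak2 3.86 FPKM, against 4.11 to 4.13 FPKM. In WT replicate 3 Cdhr3 measured 0.297 FPKM, against 0.119 to 0.146 FPKM, and in WT replicate 4 the nuclear oxidative phosphorylation score was -0.086, against 0.05 to 0.07. In Kat6a+/- replicate 2 the Wnt/beta-catenin target score was 0.076, against -0.05 to -0.03 in the other Kat6a+/- libraries, the microglia score 0.073, against -0.06 to -0.04, and Grem1 measured 1.72 FPKM, against 2.13 to 2.21 FPKM. In Kat6a+/- replicate 4 the Cajal-Retzius and subicular score was -0.20, against 0.03 to 0.06.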

How the results depend on the processing

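Alternatives with edgeR, DESeq2, a common sum without mitochondrial genes for the lists, and the removal of WT replicate 1 and Kat6a+/- replicate 2 together were chosen after the data were seen. Kat6a stayed lower in all 25 alternatives (log2 fold change -0.40 to -0.30), passed the adjusted threshold in DESeq2 alone, at -0.38 on the same genes and -0.38 on genes with over 1 read, and Rspo2 stayed lower in all 25 (-0.41 to -0.24; -0.24 without WT replicate 1) without passing. The number of called genes was 5 with DESeq2 on the same genes, 1 (Kat6a) with DESeq2 on genes with over 1 read, and 0 to 1 when leaving out each replicate (1 without WT replicate 3, Gm25654, and 1 without Kat6a+/- replicate 3, Gm25819, named after its values were seen); it was 0 without WT replicate 1 and Kat6a+/- replicate 2 together and in all other alternatives. The genes at an unadjusted p under 0.05 ran from 515 to 778 when leaving out each replicate. They were 1202 without a filter, where more genes are tested, and 339 with a common sum without mitochondrial genes. The cause of the last count was not tested. Camera called 13 lists, 0 with an estimated correlation, 0 by fry (lowest adjusted p = 0.154), 8 to 16 when leaving out each replicate (8 without WT replicate 1 and 8 without WT replicate 3) and 9 without WT replicate 1 and Kat6a+/- replicate 2 together; the estimated correlation, 0.04 to 0.86 in the called lists, widens the error of a list, and other causes were not tested. The ribosomal and interneuron lists were called lower in 15 of 17 alternatives, all but those with an estimated correlation and by fry. Of the 30 lists not called, 6 were called in at least 1 alternative: immediate early genes and neuropeptides lower, CA3 and postsynaptic genes higher, meningeal and heat shock genes lower in 1 each, while the meningeal test turned to higher without WT replicate 1 (adjusted p = 0.0545; range over the alternatives 0.0459 to 0.895) and without WT replicate 1 and Kat6a+/- replicate 2 together.

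Of the authors' genes, 342 had an unadjusted p under 0.05 in limma in place of 0 past the adjusted threshold, and 197 without WT replicate 1 and Kat6a+/- replicate 2 together, where 6 libraries are left. Tshz2 turned to 0.082 without WT replicate 1, from -0.31 in another leave-one-out fit, and to 0.066 without WT replicate 1 and Kat6a+/- replicate 2 together. Hba-a1 ran from -0.15 to 0.10 when leaving out each replicate and was 0.0019 without WT replicate 1 and Kat6a+/- replicate 2 together; the cause was not tested, and neither gene passed in any alternative. When leaving out each replicate the log2 fold change moved by over 1.5 times in 38 of 96 named genes, none of them past the threshold in limma, and turned in 2 (Tshz2 and Hba-a1). Of the other values of named genes over the alternatives, 2327 kept their direction and their side of the threshold and 5 passed it. Median-of-ratios scaling multiplied all libraries by the same factor, 1.00393, and so tested nothing. No scaling moved the median log2 fold change of all genes by over 0.1.

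The correlations did not show that each replicate number pairs the samples. Same-numbered libraries had correlations of 0.17, -0.07, 0.07 and 0.01, and 2 of 8 libraries correlated best with their own number. These correlations compare single numbers, so they cannot decide on a structure shared by several numbers. The split by replicate number described above, with 1917 genes at an unadjusted p under 0.05, is such a structure. With a replicate block 0 genes were called, 770 had an unadjusted p under 0.05 and 15 lists were called, among them CA3 pyramidal markers higher (adjusted p = 0.0215; range over the alternatives 0.0104 to 0.956) and immediate early genes lower, neither called without the block. Depth limits genes with few reads such as Gm25654 and Erfe, whose values rest on 7 and 21 reads in all. Dynlrb2, with 3 to 17 reads per library, is limited in the same way.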

Other observations

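The tests of Kat6a and of the interneuron list in this part were chosen after the result was seen.

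Immediate early genes spread widely within each genotype, and for Fos replicates 1 and 2 of both genotypes held the higher values. Fos, a transcription factor induced by neuronal activity, measured 8.92, 9.20, 3.35 and 3.69 FPKM in WT replicates 1 to 4 and 7.15, 5.93, 3.64 and 3.46 FPKM in Kat6a+/- replicates 1 to 4. Arc, a postsynaptic protein gene induced by activity, measured 44.8, 63.1, 23.0 and 23.1 FPKM in WT and 39.5, 32.2, 22.1 and 28.3 FPKM in Kat6a+/-, and Npas4 4.45, 6.14, 2.13 and 1.25 FPKM and 4.35, 2.51, 1.30 and 2.57 FPKM. Egr1 spanned 22.7 to 39.7 FPKM in WT, and its heterozygote mean was 101% of the WT mean.

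Interneuron markers were called lower in the heterozygotes by camera with the preset correlation and not with an estimated one (adjusted p = 0.242; range over the alternatives 3.27e-06 to 0.242). The values argue against tissue taken with WT replicate 1 as the cause. That library had a list score of 0.05, inside the 0.03 to 0.11 of the other WT libraries. The median log2 fold change of the list was -0.10 both with and without that library. At the preset correlation the list was still called lower without it (camera, adjusted p = 3.31e-06), but that call depends on the preset and does not decide the question by itself. Fewer interneurons of every class stays open: the mean of Gad1, Gad2 and Slc32a1 differed by -0.083 on the log2 scale (exact permutation p = 0.114) and that of the other 15 members by -0.13 (exact permutation p = 0.0286), and the gap of 0.04 between them cannot be told apart from 0 (exact permutation p = 0.257) with 4 libraries per genotype. The score of the list separated the genotypes with the smallest exact permutation p that is possible, 0.0286, which is 0.410 after adjustment over 43 lists. A lower expression of class-specific genes such as Lhx6 and Calb2 with genotype is one hypothesis, untested here, which counts of labelled interneurons per class and expression per cell would decide.

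Kat6a stood at 76.7% of WT, above the 50% that the loss of 1 of 2 equal alleles would leave. A library with the wrong genotype label is argued against, as the highest Kat6a+/- value was 0.893 of the lowest WT value. Shrinkage by the pseudocount or scaling is argued against as well, since no other pseudocount or scaling gave a log2 fold change below -0.40. That value, the lowest over all alternatives, came from leaving out 1 library. Transcript of the targeted allele that is still counted stays open, because the values are per gene and not per exon; it cannot be told apart from higher expression of the intact allele, and the 95% interval of the remaining level, 69.6% to 86.9% on the log2 scale, leaves room for both. A higher output of the intact allele is a biological hypothesis that was not tested and that reads per exon or per allele would decide.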
